A study of Mus musculus with 38 samples.

How the data were processed

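The samples were 38 one-color Affymetrix mouse arrays, hybridized with biotin-labelled RNA after a 2-cycle amplification, per the labels. Of these, 20 were from adult cortex (bound RNA of 5 reporter lines, 3 arrays each, and 5 arrays of total RNA) and 18 from tumours (bound RNA of Olig2 cells and total RNA of 3 models, 3 arrays each). The strains were mixtures of C57BL/6J, FVB and Swiss-Webster. Per the labels, cortex samples were pools of at least 2 mice. For tumours none is stated. A p value uses 1 spread per gene over all 12 groups of arrays, not only those compared. The median gene SD was 0.052 in neurons but 0.487 in Recruited tumour total RNA. The deposited values are log2 GCRMA signals, per the submitters' notes (no version given). Each group shared its own minimum, so GCRMA was run separately in each. That can narrow the spread between replicates, which was not measured, and leaves the scale between groups open.

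The plan written before the data were examined took the deposited values as the main scale and quantile normalization over all 38 arrays as an alternative. After the separate minima were seen, the 2 were exchanged: the main values are the deposited log2 values after quantile normalization over the 38 arrays, and the deposited values are an alternative. Of 16395 probe sets, 64 were array controls, 687 had no gene and 15644 had 1 gene each; none had several genes and each gene had 1 probe set. Symbols were matched to the RefSeq table for 15617 genes and 0 changed. Other columns not used numbered 0. Genes above log2 50 (5.64) in at least 3 arrays were tested, 9799 in number, and 5845 were removed. A level under that limit is called dim.

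Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of the 12 groups over all arrays (26 residual degrees of freedom, eBayes with a constant prior), with Benjamini-Hochberg adjustment over the tested genes in each comparison. A gene passed with an adjusted p under 0.05 and a change of at least 2-fold. The 18 comparisons were each cortical population against cortex total RNA; progenitors against mature oligodendrocytes; bound against total RNA in each tumour model; tumour Olig2 cells, as a mean of the models and by model, against cortical Olig2 cells; each pair of models in bound RNA; tumour against cortex total RNA; and the difference of bound over total RNA between tumours and cortical Olig2 cells. The last was also tested between pairs of models.

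Whether bound and total RNA of the same number belonged together was checked by the correlation, over genes, of each array's deviation from its group mean. Same-numbered arrays correlated in each tumour model: 0.626, 0.618 and 0.473 for Pdgf, 0.621, 0.428 and 0.555 for Pdgf Cre and 0.466, 0.266 and 0.488 for Recruited. The main model leaves these pairs out, also where ratios of bound to total RNA are compared, and alternatives fit the pair as a block.

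The 29 gene lists, with 407 entries, were written from general knowledge before the files were seen; 338 entries were measured and 284 tested. They were the neuron markers, astrocyte markers, mature oligodendrocyte and myelin markers, committed oligodendrocyte precursor markers, oligodendrocyte progenitor markers, microglia and macrophage markers, lymphocyte and granulocyte markers, endothelial markers, pericyte, smooth muscle and fibroblast markers, ependymal and choroid plexus markers, neural stem and immature neural genes, DNA replication genes, mitosis genes, cell cycle inhibitor and quiescence genes, cholesterol synthesis genes, hypoxia and glycolysis genes, type I interferon response genes, antigen presentation genes, extracellular matrix and mesenchymal genes, receptor tyrosine kinase signalling and feedback genes, Wnt pathway genes, BMP and TGF-beta pathway genes, Hedgehog pathway genes, p53 target genes, ribosomal protein genes, oxidative phosphorylation genes, nuclear noncoding RNAs, immediate early genes and Notch pathway genes. Each list was tested with camera of limma with a preset correlation between genes of 0.01 and with an estimated correlation, and adjusted by Benjamini-Hochberg over the 522 tests of lists. With an estimated correlation no list held. The genes high in progenitors or in mature oligodendrocytes were, of the genes that passed between the 2, the 200 with the largest moderated t on each side, so genes with a large difference but a wide spread can be missing. The arrays of the 2 stages are not among those of the tumour comparisons. But the spread in the moderated t came from all 38 arrays, tumours included, so the sets are not independent of them.

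Named genes were taken by a rule fixed beforehand: the genes of the 5 reporter lines; the 10 largest rises and falls among genes that passed, whose replicates did not overlap between groups, with both means above the dim limit and with a gene symbol other than a clone name; and up to 4 members of each described list with the largest change. The comparison of bound over total ratios was left out of the part on largest rises and falls. Ttr, H19, Wsb1, Xist and Eif2s3y in the closing section were chosen after their values were seen.

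In simulated data with the same groups, 79% to 99% of 100 genes changed by a log2 difference of 1.5 were recovered by comparison. Of 100 changed by 3, 93% to 100% were. Of 9599 unchanged genes 1 to 8 passed. This leaves error in the real arrays open. Alternatives were the deposited values, no filter on dim genes, a dim limit of 100, a trended and robust prior, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were scaling by the 18 hybridization control probe sets, called spike-in scaling, leaving out pair 3 of the Recruited tumour, and the pair as a block for ratios between models. Between 7383 and 7398 genes per array lay above the dim limit as group means, and the number of arrays limits the precision. The signal difference between 3′ and 5′ probes of actin and Gapdh, the poly-A controls and the correlation between replicates were read as quality measures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.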

Results

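The series held 38 mouse arrays of RNA bound to tagged ribosomes of 1 cell population or of total RNA from the same kind of tissue. Bound RNA of adult cortex came from 5 reporter lines, with n = 3 arrays each: Snap25 (neurons), Cnp (mature oligodendrocytes), Aldh1l1 (astrocytes), Pdgfra (progenitors) and Olig2 (cells of the oligodendrocyte lineage). Total RNA of cortex had n = 5 arrays. From glioma-bearing mice came bound RNA of Olig2 cells and total RNA in 3 tumour models, named Pdgf, Pdgf Cre and Recruited by the submitters, with n = 3 arrays for each. The questions were which transcripts each cortical population carries above its tissue, which ones the Olig2 cells of the tumours carry above theirs, how tumour Olig2 cells differ from cortical Olig2 cells and from each stage of the lineage, and how the 3 models differ. Levels below are log2 after a common quantile normalization, given as mean ± SD over arrays. A gene is said to rise or fall where the limma adjusted p was under 0.05 and the change at least 2-fold. Where 1 side lay under the dim limit of log2 50, the fold is given as at least the ratio to that limit, and list medians are given also with dim levels raised to it (at the dim limit) where the 2 part by more than 0.1. The separate GCRMA of each group of arrays can make the spread between its replicates, and so the p values, too small, and this was not measured.

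**Figure D1:**
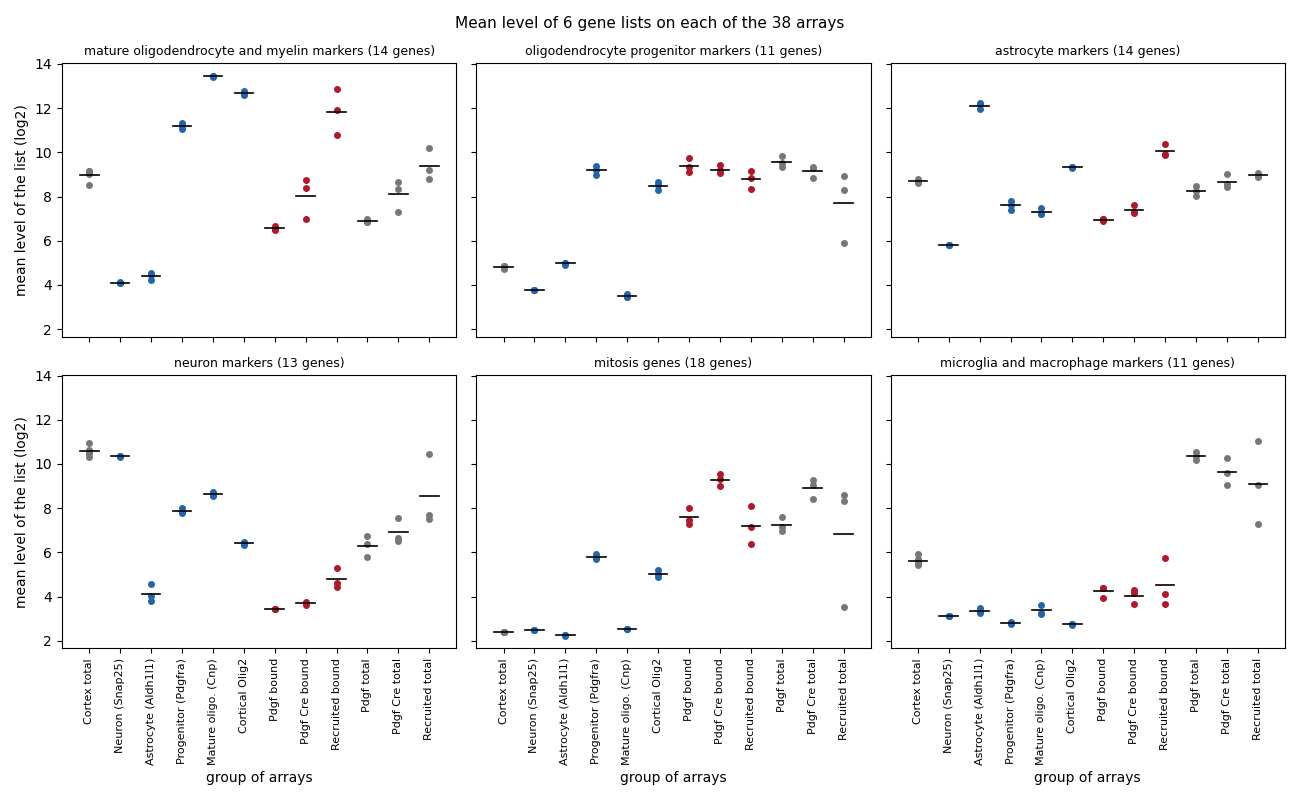
Mean log2 level of 6 gene lists in each of the 38 arrays, by group. Grey points are total RNA, blue points bound RNA of cortex, red points bound RNA of tumours, and black lines the group means.

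Bound RNA of neurons was low in transcripts of glia against cortex total RNA (n = 3 against 5). Apoe, a lipid carrier made largely by astrocytes, fell 47.1-fold (log2 difference -5.56 ± 0.30 SE), and the gap junction gene Gja1 fell 25.1-fold. Fabp7, Ptgds, Selenop and Il33 fell 20.98-fold, 22.7-fold, 22.7-fold and 17.6-fold, and the myelin gene Mbp fell 17.1-fold (log2 difference -4.09 ± 0.22 SE). All 14 of 14 mature oligodendrocyte and myelin markers fell (median log2 difference -5.20, or -3.47 at the dim limit, camera adjusted p = 6.83e-08, and adjusted p = 0.49 with an estimated correlation), among them Mog (at least 11.7-fold), Cldn11 (at least 10.4-fold) and Opalin (at least 12.1-fold). Among the astrocyte markers 12 of 14 fell (median log2 difference -2.72, or -2.001 at the dim limit, camera adjusted p = 3.25e-07, and adjusted p = 0.231 with an estimated correlation). Gjb6 fell at least 13.8-fold and Acsbg1 at least 7.43-fold. Microglia and macrophage markers fell in 7 of 11 and rose in 1 (median log2 difference -3.41, or -0.08 at the dim limit, camera adjusted p = 0.0228, and adjusted p = 0.888 with an estimated correlation). Ctss fell 12.3-fold. Committed oligodendrocyte precursor markers fell in 5 of 9 and rose in 1 (median log2 difference -1.71, or -0.20 at the dim limit, camera adjusted p = 0.0211, and adjusted p = 0.71 with an estimated correlation). Gpr17 fell at least 9.21-fold.

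Neural stem and immature neural genes fell in neurons for 4 of 8 (median log2 difference -1.39, or -1.19 at the dim limit, camera adjusted p = 0.0228, and adjusted p = 0.644 with an estimated correlation), Sox2 by 4.49-fold. Each of the counts in neurons was the same when adjusted over the list alone. The neuron markers themselves did not rise: 1 of 13 fell, Gad2 by at least 2.84-fold, and the other 12 did not pass (median log2 difference 0.02, mean -0.23, test direction down, camera adjusted p = 0.583). Snap25, the gene of the reporter line, stood at 15.46 ± 0.09 in bound RNA and 15.22 ± 0.07 in total RNA (log2 difference 0.24 ± 0.30 SE, adjusted p = 0.534). The largest rises were in Ppil1 (6.56-fold, log2 difference 2.71 ± 0.31 SE), the tubulin gene Tuba8 (5.97-fold) and the actin-binding gene Pfn1 (5.72-fold). In all 2765 genes passed, 1312 higher and 1453 lower. With the values as deposited, the median gene lay 0.66 above cortex total RNA and 4774 genes passed, 75.4% of them higher against 47.5% here.

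Bound RNA of astrocytes carried the transcripts of astrocytes far above cortex total RNA (n = 3 against 5). Aldh1l1, the gene of the line, rose 9.16-fold (log2 difference 3.20 ± 0.40 SE), and Fxyd1, a regulator of the sodium pump, rose 118-fold (log2 difference 6.88 ± 0.39 SE). Mdk, Mgst1, S100a1 and Ndp rose 85.8-fold, 65.2-fold, 64.03-fold and 45.3-fold. All 14 of 14 astrocyte markers rose (median log2 difference 3.08, camera adjusted p = 0.00031, and adjusted p = 0.47 with an estimated correlation). The glutamate transporter Slc1a2 rose at least 71.9-fold, Slc1a3 26.4-fold and the water channel Aqp4 at least 18.4-fold. Neuron markers fell in 13 of 13 (median log2 difference -6.15, or -5.34 at the dim limit, camera adjusted p = 0.000131, and adjusted p = 0.701 with an estimated correlation). Stmn2 fell at least 112-fold and Syn1 at least 57.01-fold; Chgb, a granule protein of neurons, fell 146-fold (log2 difference -7.19 ± 0.40 SE) and Gad1 fell 65.6-fold. Mature oligodendrocyte and myelin markers fell in 13 of 14 (median log2 difference -5.18, or -3.47 at the dim limit, camera adjusted p = 0.0013, and adjusted p = 0.734 with an estimated correlation). Trf fell at least 26.2-fold.

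Genes of 3 signalling pathways rose in astrocytes together. Notch pathway genes rose in 8 of 10 (median log2 difference 2.85, or 2.09 at the dim limit, camera adjusted p = 0.022, and adjusted p = 0.665 with an estimated correlation). Hes5 rose 17.3-fold and Hey2 16.97-fold. Of the BMP and TGF-beta pathway genes 10 of 14 rose and 3 fell (median log2 difference 3.74, or 2.27 at the dim limit, camera adjusted p = 0.0492, and adjusted p = 0.47 with an estimated correlation). Id3 rose 29.3-fold and Id1 at least 14.8-fold. Hedgehog pathway genes rose in 3 of 5 (median log2 difference 4.78, or 2.65 at the dim limit, camera adjusted p = 0.0403, and adjusted p = 0.49 with an estimated correlation). Smo rose at least 12.2-fold and Gli3 at least 13.1-fold. Cell cycle inhibitor and quiescence genes rose in 9 and fell in 2 of 11 (median log2 difference 2.81, or 2.16 at the dim limit, camera adjusted p = 0.111), Cdkn2c by at least 20.7-fold and Gas1 by 28.9-fold. The ependymal and choroid plexus markers rose in 4 of 5 (median log2 difference 2.68, or 1.41 at the dim limit, camera adjusted p = 0.134), Ttr among them at 10.65 ± 2.85 against 6.005 ± 3.36, with a wide spread between arrays. Counts for these astrocyte lists were the same when adjusted over the list alone. In all 5973 genes passed, 51.03% of them higher, and with spike-in scaling, added after the data were seen, 34.03%.

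Bound RNA of mature oligodendrocytes was rich in myelin transcripts (n = 3 against 5). Cnp, the gene of the line, rose 31.9-fold (log2 difference 4.996 ± 0.40 SE); Cd9 and Tmem125, membrane proteins of myelinating cells, rose 112-fold (log2 difference 6.80 ± 0.43 SE) and 112-fold; Gpr37, Jam3, Ppp1r14a and Evi2a rose 75.2-fold, 80.9-fold, 61.7-fold and 63.1-fold. All 14 of 14 mature oligodendrocyte and myelin markers rose (median log2 difference 4.14, camera adjusted p = 0.000128, and adjusted p = 0.701 with an estimated correlation). Mobp rose at least 51.1-fold, Mag 48.4-fold, Mog 41.4-fold and Aspa 37.9-fold. Olig2 rose 29.5-fold. Astrocyte markers fell in 9 of 14 and rose in 1 (median log2 difference -1.48, or -0.95 at the dim limit, camera adjusted p = 0.0464, and adjusted p = 0.719 with an estimated correlation). Slc4a4 fell 8.13-fold and Sox9 at least 2.79-fold. Neuron markers fell in 10 of 13 (median log2 difference -1.84, camera adjusted p = 0.0564). Rbfox3 fell 8.87-fold and Nefl 5.39-fold. The largest falls were in Gng13 (23.7-fold, log2 difference -4.57 ± 0.87 SE), the spectrin gene Sptan1 (21.4-fold) and Cplx2 (17.7-fold), while Snap25 stayed high at 14.04 ± 0.10 against 15.22 ± 0.07 and fell 2.27-fold. In mature oligodendrocytes the list counts were the same when adjusted over the list alone. In all 5181 genes passed, 2465 higher and 2716 lower.

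Bound RNA of progenitors carried genes of progenitors, of committed precursors and, less strongly, of myelin (n = 3 against 5). Pdgfra, the gene of the line, rose at least 26.03-fold, at 10.35 ± 0.04 against 4.77 ± 0.07, and Olig2 rose 68.9-fold (log2 difference 6.11 ± 0.35 SE). Cav1, Ostf1, Spry1 and Lims2 rose 69.2-fold, 69.8-fold, 56.2-fold and 40.3-fold. Oligodendrocyte progenitor markers rose in 10 of 11 (median log2 difference 4.23, or 3.03 at the dim limit, camera adjusted p = 0.000519, and adjusted p = 0.71 with an estimated correlation). Matn4 rose at least 18.7-fold, Cspg4, which codes for the NG2 proteoglycan, at least 15.2-fold, Rlbp1 49.5-fold and Lhfpl3 47-fold. All 9 of 9 committed oligodendrocyte precursor markers rose (median log2 difference 3.18, or 2.42 at the dim limit, camera adjusted p = 0.000647, and adjusted p = 0.49 with an estimated correlation). Gpr17 rose 36.8-fold and Bmp4 12.6-fold. All 14 of 14 myelin markers rose as well (median log2 difference 2.24, camera adjusted p = 0.0118, and adjusted p = 0.819 with an estimated correlation). Mag rose 8.33-fold and Ugt8a 6.77-fold.

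Dividing-cell genes rose in progenitors too. Mitosis genes rose in 16 of 18 (median log2 difference 3.50, or 0.17 at the dim limit, camera adjusted p = 0.0107, and adjusted p = 0.969 with an estimated correlation). Nusap1 rose at least 7.47-fold and Prc1 at least 7.23-fold. DNA replication genes rose in 12 and fell in 2 of 14 (median log2 difference 3.29, or 0.98 at the dim limit, camera adjusted p = 0.0564). Rrm2 rose at least 30.2-fold and Mcm6 17.3-fold. Receptor tyrosine kinase signalling and feedback genes rose in 8 and fell in 2 of 11 (median log2 difference 2.48, or 0.00 at the dim limit, camera adjusted p = 0.165), the cyclin gene Ccnd1 by 19.3-fold. Of the neuron markers 13 of 13 fell (median log2 difference -2.98, or -2.33 at the dim limit, camera adjusted p = 0.00434, and adjusted p = 0.734 with an estimated correlation), Nefl by 11.6-fold, and microglia and macrophage markers in 8 of 11 (median log2 difference -2.86, or -0.08 at the dim limit, camera adjusted p = 0.0329, and adjusted p = 0.899 with an estimated correlation), Tyrobp by at least 4.31-fold. Ttr, a gene of choroid plexus, stood at 13.46 ± 1.42 against 6.005 ± 3.36 (adjusted p = 0.00159, not passed with the replicate number as a block). In progenitors the list counts were the same when adjusted over the list alone. In all 4722 genes passed, 2390 higher and 2332 lower. The progenitor arrays had the highest 3′ minus 5′ signal of the actin control among the groups, 6.48 ± 0.47 against 4.57 ± 1.01 in cortex total RNA.

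Bound RNA of cortical Olig2 cells held genes of every stage of the oligodendrocyte lineage (n = 3 against 5). Olig2 rose 78.2-fold (log2 difference 6.29 ± 0.35 SE), Cnp rose 16.7-fold and Pdgfra rose at least 9.18-fold. Tmem125, Pdlim2, Cd9 and S100a1 rose 88.6-fold, 69.2-fold, 68.3-fold and 47.4-fold. All 14 of 14 myelin markers rose (median log2 difference 3.40, camera adjusted p = 0.0014, and adjusted p = 0.734 with an estimated correlation). Mobp rose at least 51.3-fold and Mog 23.6-fold. All 9 of 9 committed precursor markers rose (median log2 difference 4.18, or 2.79 at the dim limit, camera adjusted p = 0.00176, and adjusted p = 0.553 with an estimated correlation). Gpr17 rose 23.3-fold and Cnksr3 23.3-fold, and 9 of 11 progenitor markers rose (median log2 difference 4.02, or 2.56 at the dim limit, camera adjusted p = 0.0124, and adjusted p = 0.796 with an estimated correlation). Matn4 rose at least 7.46-fold and Cspg4 at least 7.93-fold. Mitosis genes rose in 13 of 18 (median log2 difference 2.69, or 0.00 at the dim limit, camera adjusted p = 0.094), Cdk1 by at least 2.90-fold. All 13 of 13 neuron markers fell (median log2 difference -4.10, or -3.84 at the dim limit, camera adjusted p = 0.000595, and adjusted p = 0.71 with an estimated correlation). Tbr1 fell at least 40.5-fold and Nefl 31.5-fold. Aldh1l1 did not pass (log2 difference 0.76 ± 0.40 SE, adjusted p = 0.0804), though 5 of 14 astrocyte markers rose and 2 fell (median log2 difference 0.54, or 0.39 at the dim limit, camera adjusted p = 0.483), S100b by 15.7-fold. In cortical Olig2 cells the list counts were the same when adjusted over the list alone. In all 5498 genes passed, 52.5% of them higher, and 40.2% with spike-in scaling.

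Nuclear noncoding RNAs fell in bound RNA of all 5 populations, 3 of 3 in each. Meg3 stood at 12.17 ± 0.43 in cortex total RNA and at 4.09 ± 0.10 in neurons, 2.70 ± 0.03 in astrocytes, 4.92 ± 0.43 in mature oligodendrocytes, 5.22 ± 0.01 in progenitors and 3.40 ± 0.17 in Olig2 cells, so it fell at least 92.2-fold in each. Snhg11 fell at least 29.4-fold in each. The list medians of log2 difference, in the same order of populations, were -5.07, -8.21, -7.25, -6.51 and -8.21, and -4.88 in each at the dim limit. The camera tests gave, in the same order, adjusted p = 0.0014, and adjusted p = 0.165 with an estimated correlation; adjusted p = 0.0329, and adjusted p = 0.417 with an estimated correlation; adjusted p = 0.02, and adjusted p = 0.311 with an estimated correlation; adjusted p = 0.0121, and adjusted p = 0.311 with an estimated correlation; adjusted p = 0.019, and adjusted p = 0.311 with an estimated correlation. The counts were the same when adjusted over the list alone.

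Progenitors and mature oligodendrocytes were compared directly to ask which genes part the ends of the lineage (n = 3 each). Pdgfra was higher in progenitors by at least 26.03-fold, and Rlbp1, Gpr17 and Rgcc by 159.6-fold (log2 difference 7.32 ± 0.52 SE), 97.6-fold and 78-fold. The transcription factor gene Zeb1 was higher by 51.6-fold and Scrg1 by 48.6-fold. All 11 of 11 progenitor markers were higher (median log2 difference 6.80, or 4.12 at the dim limit, camera adjusted p = 5.93e-06, and adjusted p = 0.553 with an estimated correlation). Lhfpl3 rose at least 145-fold and Ptprz1 at least 23.1-fold. Committed precursor markers were higher in 7 of 9 (median log2 difference 2.56, or 1.60 at the dim limit, camera adjusted p = 0.00192, and adjusted p = 0.553 with an estimated correlation). Bmp4 rose at least 21.3-fold. Neural stem and immature neural genes rose in 6 of 8 (median log2 difference 3.15, or 1.99 at the dim limit, camera adjusted p = 0.00127, and adjusted p = 0.47 with an estimated correlation). Sox11 rose at least 12.4-fold, Fabp7 46.03-fold and Sox2 25.9-fold. Notch pathway genes rose in 7 of 10 (median log2 difference 3.62, or 2.53 at the dim limit, camera adjusted p = 0.00198, and adjusted p = 0.49 with an estimated correlation). Hes5 rose at least 25.4-fold and Nrarp 45.3-fold.

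The division genes also parted the ends of the lineage: 14 of 18 mitosis genes (median log2 difference 3.25, or 0.17 at the dim limit, camera adjusted p = 0.00437, and adjusted p = 0.952 with an estimated correlation) and 9 of 14 DNA replication genes (median log2 difference 2.02, or 0.86 at the dim limit, camera adjusted p = 0.019, and adjusted p = 0.888 with an estimated correlation) were higher in progenitors, with Nusap1 up at least 7.47-fold and Rrm2 at least 30.2-fold. In mature cells 11 of 14 myelin markers were higher (median log2 difference -2.29, camera adjusted p = 0.0117, and adjusted p = 0.819 with an estimated correlation), so that Mobp fell 27.4-fold (log2 difference -4.78 ± 0.57 SE) in progenitors, Mog 10.3-fold and Aspa 9.35-fold. Serpinb1a fell 40.3-fold (log2 difference -5.33 ± 0.13 SE), Tppp3 40.1-fold, Ptgds 26.8-fold and Cnp 6.95-fold. The 3′ minus 5′ signal of actin also differed, 6.48 ± 0.47 in progenitors against 3.39 ± 0.08. Olig2 differed less, 2.33-fold higher in progenitors. Ribosomal protein genes rose in 2 of 8 (median log2 difference 0.56, camera adjusted p = 0.19), Rpl22 by 2.71-fold. Along the lineage the list counts were the same when adjusted over the list alone except 16 higher and 0 lower for the mitosis genes and 11 higher and 0 lower for the DNA replication genes. In all 3792 genes passed, 48.6% higher in progenitors; the share was 35.4% with the deposited values, where the median gene shifted by -0.38, and 31.7% with spike-in scaling.

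Tumour bound RNA was set against tumour total RNA to ask which transcripts the Olig2 cells hold above the whole tumour (n = 3 against 3 in each model). In the Pdgf tumour markers of other cell types fell. The complement gene C1qb, made by microglia, fell 41.6-fold (log2 difference -5.38 ± 0.73 SE), Tyrobp 33.6-fold, Ctss 30.4-fold, Selenop 28.04-fold and the matrix gene Bgn 23.1-fold. All 11 of 11 microglia and macrophage markers fell (median log2 difference -5.59, or -4.93 at the dim limit, camera adjusted p = 4.33e-07, and adjusted p = 0.533 with an estimated correlation). Csf1r fell at least 35.3-fold. All 10 of 10 pericyte, smooth muscle and fibroblast markers (median log2 difference -4.49, or -1.43 at the dim limit, camera adjusted p = 5.84e-05, and adjusted p = 0.47 with an estimated correlation) and 3 of 3 endothelial markers (median log2 difference -4.67, or -1.60 at the dim limit, camera adjusted p = 0.00623, and adjusted p = 0.451 with an estimated correlation) fell, with Col3a1 down at least 11.5-fold and Cldn5 at least 14.2-fold. Neuron markers fell in 10 of 13 (median log2 difference -3.11, or -1.17 at the dim limit, camera adjusted p = 0.00112, and adjusted p = 0.719 with an estimated correlation). Stmn2 fell at least 13.4-fold. Astrocyte markers fell in 5 and rose in 1 of 14 (median log2 difference -0.74, or -0.32 at the dim limit, camera adjusted p = 0.0118, and adjusted p = 0.665 with an estimated correlation). Gja1 fell 17.6-fold. Extracellular matrix and mesenchymal genes fell in 8 of 11 and rose in 1 (median log2 difference -2.02, camera adjusted p = 0.0464, and adjusted p = 0.834 with an estimated correlation). Sparc fell 6.11-fold. Olig2 stood at 12.39 ± 0.14 in bound and 12.12 ± 0.11 in total RNA (log2 difference 0.27 ± 0.40 SE, adjusted p = 0.603), and Pdgfra fell 4.09-fold (log2 difference -2.03 ± 0.50 SE).

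Rises in bound RNA of the Pdgf tumour were smaller, with the splicing gene Snrpd1 up 11.1-fold (log2 difference 3.47 ± 0.20 SE), Bri3 7.51-fold (not with the pair as a block) and the mitochondrial genes Sdhc 6.11-fold and Mrps11 6.49-fold. Mitosis genes barely parted bound from total RNA (1 of 18 rose; median log2 difference 0.22, camera adjusted p = 0.934). The list counts of the Pdgf tumour were the same when adjusted over the list alone except 0 higher and 0 lower for the mitosis genes. In all 3157 genes passed, 52.4% of them higher, but 17.9% with the deposited values, where the median gene shifted by -0.34, and 21.9% with spike-in scaling. The poly-A controls of the Pdgf total RNA stood at 3.92 ± 0.66 against 6.86 ± 1.85 in its bound RNA.

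In the Pdgf Cre tumour, too, markers of other cell types fell (n = 3 against 3). C1qb fell 72.7-fold (log2 difference -6.18 ± 0.73 SE), Bgn 41.7-fold, Ctss 35.99-fold and the neuronal surface gene Thy1 31.5-fold, and Ttr stood at 8.87 ± 1.005 in bound against 14.28 ± 0.67 in total RNA. All 11 of 11 microglia and macrophage markers (median log2 difference -5.17, or -3.41 at the dim limit, camera adjusted p = 7.14e-06, and adjusted p = 0.644 with an estimated correlation), 8 of 10 pericyte, smooth muscle and fibroblast markers (median log2 difference -5.21, or -1.93 at the dim limit, camera adjusted p = 0.000519, and adjusted p = 0.49 with an estimated correlation) and 3 of 3 endothelial markers (median log2 difference -3.90, or -1.38 at the dim limit, camera adjusted p = 0.0112, and adjusted p = 0.47 with an estimated correlation) fell, with Tyrobp down at least 81.2-fold, Dcn at least 9.59-fold and Cldn5 at least 8.24-fold. Neuron markers fell in 12 of 13 (median log2 difference -2.98, or -1.06 at the dim limit, camera adjusted p = 0.000246, and adjusted p = 0.701 with an estimated correlation). Gad1 fell 17.1-fold. Nuclear noncoding RNAs fell in 3 of 3 (median log2 difference -5.99, or -2.42 at the dim limit, camera adjusted p = 0.000185, and adjusted p = 0.0594 with an estimated correlation). Meg3 fell at least 60.8-fold. Olig2 rose 2.41-fold (log2 difference 1.27 ± 0.40 SE), Krt1 13.8-fold, Snrpd1 13.3-fold and Angptl6 8.17-fold. The list counts of the Pdgf Cre tumour were the same when adjusted over the list alone. In all 3726 genes passed, 52.5% higher, but 23.3% with the deposited values (median gene shifted by -0.21) and 32.7% with spike-in scaling.

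The Recruited tumour differed in that its bound RNA was rich in myelin genes against its own total RNA (n = 3 against 3). Ppp1r14a rose 26.8-fold (log2 difference 4.74 ± 0.71 SE), Opalin 24.6-fold (log2 difference 4.62 ± 0.75 SE), S1pr5 18.8-fold, Tmem100 18.1-fold and Scrg1 13.7-fold, with Cnp up 4.19-fold and Olig2 2.52-fold (not with the pair as a block). Myelin markers rose in 12 of 14 (median log2 difference 2.27, camera adjusted p = 0.019, and adjusted p = 0.866 with an estimated correlation). Mag rose 8.87-fold and Mog 7.89-fold. Committed precursor markers rose in 7 and fell in 1 of 9 (median log2 difference 1.68, camera adjusted p = 0.0542). Gpr17 rose 8.40-fold. Cholesterol synthesis genes rose in 8 of 10 (median log2 difference 1.36, or 1.26 at the dim limit, camera adjusted p = 0.0564), Msmo1 by 3.84-fold and Cyp51 by 3.26-fold. Microglia markers fell in 11 of 11 (median log2 difference -4.69, or -3.47 at the dim limit, camera adjusted p = 0.000264, and adjusted p = 0.71 with an estimated correlation), neuron markers in 12 of 13 (median log2 difference -4.22, or -2.04 at the dim limit, camera adjusted p = 8.24e-05, and adjusted p = 0.665 with an estimated correlation) and pericyte, smooth muscle and fibroblast markers in 10 of 10 (median log2 difference -3.96, or -2.95 at the dim limit, camera adjusted p = 0.00115, and adjusted p = 0.533 with an estimated correlation). Ptprc fell at least 7.90-fold, Stmn2 24.6-fold (log2 difference -4.62 ± 0.60 SE) and Col3a1 22.5-fold. Anxa1 fell 31.5-fold. Counts for the lists in the Recruited tumour were the same when adjusted over the list alone except 13 higher and 0 lower for the mature oligodendrocyte and myelin markers and 0 higher and 13 lower for the neuron markers. In all 4340 genes passed, 54.4% higher, but 31.6% with the deposited values (median gene shifted by -0.29) and 27.1% with spike-in scaling. Recruited total RNA had the lowest correlation between replicates of all groups (r from 0.861). Its array 3 was nearer cortex total RNA: neuron markers 10.45 against 10.58 (others 7.52, 7.68), mitosis genes 3.51 against 2.41 (8.34, 8.60). Without pair 3 the neuron median was -3.28. Replicates of the Recruited bound RNA were less alike than those of neurons (r from 0.930 against 0.9987). Poly-A controls stood at 3.50 ± 0.25 in its total and 7.89 ± 1.09 in its bound RNA.

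Olig2 cells of the tumours, as the mean of 3 models (n = 9 against 3), carried less of myelin and more of division genes than cortical Olig2 cells. P values for a mean of the models leave out the spread between them. The labels give no batch, so all comparisons of tumour with cortex carry any difference in handling. Ermn fell 55.9-fold (log2 difference -5.80 ± 0.41 SE), Aspa 48.1-fold, Opalin 42.4-fold, Mal 41.4-fold and Cnp 6.59-fold, and among other genes Efhd1 fell 79.4-fold (log2 difference -6.31 ± 0.35 SE) and Car2 26.6-fold. All 14 of 14 myelin markers fell (median log2 difference -4.02, or -3.68 at the dim limit, camera adjusted p = 4.33e-07, and adjusted p = 0.533 with an estimated correlation), but the models parted here, with a mean level of 6.56 ± 0.10 in Pdgf, 8.04 ± 0.92 in Pdgf Cre and 11.85 ± 1.04 in Recruited against 12.67 ± 0.08. Committed precursor markers fell in 5 of 9 with 1 higher (median log2 difference -2.01, or -0.98 at the dim limit, camera adjusted p = 0.0564). Bmp4 fell 6.42-fold. Progenitor markers rose in 5 and fell in 1 of 11 (median log2 difference 0.90, or 0.70 at the dim limit, camera adjusted p = 0.504). Ptprz1 rose 3.65-fold and Cspg4 2.92-fold; Pdgfra rose 4.14-fold (log2 difference 2.05 ± 0.41 SE), while Olig2 stood level (log2 difference 0.08 ± 0.32 SE, adjusted p = 0.864). Mitosis genes rose in 17 of 18 (median log2 difference 3.11, or 2.37 at the dim limit, camera adjusted p = 0.000197, and adjusted p = 0.819 with an estimated correlation). Aurka rose at least 5.17-fold and Kif20a at least 2.06-fold. DNA replication genes rose in 11 of 14 (median log2 difference 1.56, camera adjusted p = 0.00913, and adjusted p = 0.819 with an estimated correlation). Rrm2 rose 6.05-fold.

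Single genes of the cell cycle, of matrix and of immunity passed in the tumours as well. Cdkn2b, which codes for the inhibitor p15, rose 12.9-fold (log2 difference 3.69 ± 0.53 SE), and Cdkn1a, a target of p53 that codes for p21, rose at least 11.7-fold, though the list of cell cycle inhibitor and quiescence genes was mixed (3 higher and 1 lower of 11; median log2 difference 0.40, camera adjusted p = 0.868). Ifitm3 rose 17.7-fold (log2 difference 4.14 ± 0.70 SE), Hpgd 15.6-fold, the immunity GTPase gene Irgm1 11.8-fold and Vim 10.8-fold. Extracellular matrix and mesenchymal genes rose in 8 of 11 (median log2 difference 3.43, or 0.74 at the dim limit, camera adjusted p = 0.019, and adjusted p = 0.746 with an estimated correlation). Antigen presentation genes rose in 9 of 12 (median log2 difference 3.12, or 0.91 at the dim limit, camera adjusted p = 0.0325, and adjusted p = 0.968 with an estimated correlation). Psmb8 rose at least 7.95-fold and B2m 9.97-fold. The arrays of a model differed widely, with list means of 6.29 to 8.04 in Pdgf, 6.34 to 10.33 in Pdgf Cre and 4.68 to 10.20 in Recruited against 3.85 to 4.13 in cortical Olig2 cells. Type I interferon response genes rose in 5 of 7 (median log2 difference 2.75, or 1.22 at the dim limit, camera adjusted p = 0.175). Rtp4 rose at least 4.70-fold, and the list mean ran from 3.67 to 9.35 between Recruited arrays. Microglia and macrophage markers rose in 7 of 11 (median log2 difference 1.42, or 0.00 at the dim limit, camera adjusted p = 0.102). Ctss rose 6.25-fold. Immediate early genes rose in 6 and fell in 2 of 11 (median log2 difference 1.40, or 0.00 at the dim limit, camera adjusted p = 0.548). Egr2 rose 8.63-fold, Fos 7.10-fold, and Arc fell at least 8.27-fold.

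Neuron markers fell in tumour Olig2 cells for 13 of 13 (median log2 difference -1.91, or -0.88 at the dim limit, camera adjusted p = 0.000458, and adjusted p = 0.706 with an estimated correlation). Rbfox3 fell at least 5.31-fold. Astrocyte markers fell in 7 of 14 (median log2 difference -1.21, or -0.40 at the dim limit, camera adjusted p = 0.00732, and adjusted p = 0.644 with an estimated correlation). Gjb6 fell 17.3-fold. The Recruited tumour went the other way, with a mean level of 10.06 ± 0.27 against 9.33 ± 0.02. Oxidative phosphorylation genes did not change (0 of 14 higher, 0 lower; median log2 difference 0.05, mean -0.06, test direction up, camera adjusted p = 0.975). Wnt pathway genes rose in 1 and fell in 2 of 6 (median log2 difference -0.70, or -0.23 at the dim limit, camera adjusted p = 0.14). The p53 target genes rose in 3 and fell in 1 of 10 (median log2 difference -0.10, mean 0.41, test direction up, camera adjusted p = 0.854). Hypoxia and glycolysis genes rose in 3 and fell in 1 of 10 (median log2 difference 0.38, or 0.04 at the dim limit, mean -0.12, test direction up, camera adjusted p = 0.923). Lymphocyte and granulocyte markers held only Csf3r, dim on both sides. Counts for the lists in tumour Olig2 cells were the same when adjusted over the list alone except 13 higher and 0 lower for the DNA replication genes and 10 higher and 0 lower for the antigen presentation genes. In all 2736 genes passed, 1325 higher and 1411 lower, and with the deposited values the median gene shifted by 0.11.

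**Figure D2:**
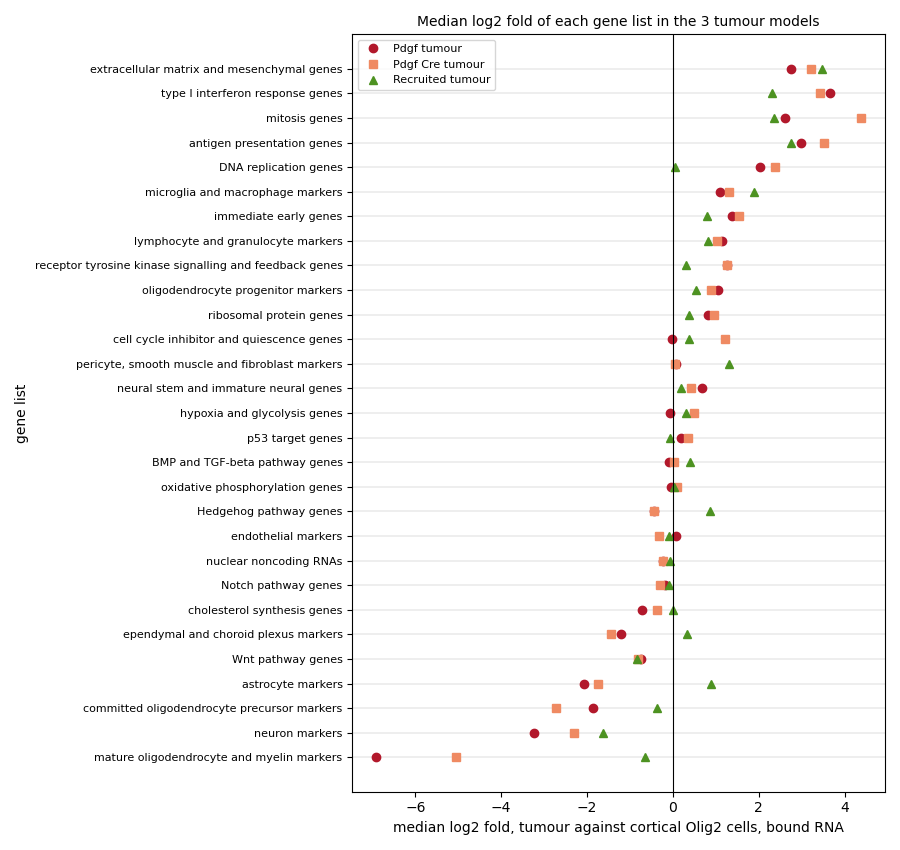
Median log2 difference of each of 29 gene lists between bound RNA of tumour Olig2 cells and of cortical Olig2 cells, by tumour model.

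Each model was then set against cortical Olig2 cells by itself (n = 3 against 3) to ask which changes it shows alone. In the Pdgf tumour the loss of myelin genes was the deepest of the 3 by median: all 14 of 14 markers fell (median log2 difference -6.90, or -5.93 at the dim limit, camera adjusted p = 1.67e-08, and adjusted p = 0.47 with an estimated correlation). Mal fell at least 533-fold and Mog at least 277-fold, and Opalin fell 182-fold (log2 difference -7.50 ± 0.75 SE), Pdlim2 103-fold and Ptgds 87.1-fold. Astrocyte markers fell in 11 of 14 (median log2 difference -2.06, or -1.15 at the dim limit, camera adjusted p = 3.57e-05, and adjusted p = 0.342 with an estimated correlation). Gja1 fell 32.6-fold, and Aldh1l1 fell at least 10.4-fold. Hpgd rose 30.9-fold (log2 difference 4.95 ± 0.68 SE), Cdkn2b 27.4-fold, the calponin gene Cnn2 19.1-fold and Igfbp3 13.4-fold. Mitosis genes rose in 16 of 18 (median log2 difference 2.61, or 1.87 at the dim limit, camera adjusted p = 0.00949, and adjusted p = 0.968 with an estimated correlation). Bub1 rose at least 1.99-fold. DNA replication genes rose in 9 of 14 (median log2 difference 2.02, or 1.83 at the dim limit, camera adjusted p = 0.0117, and adjusted p = 0.847 with an estimated correlation). Cdc45 rose 5.71-fold. Counts for the lists in this comparison were the same when adjusted over the list alone except 17 higher and 0 lower for the mitosis genes and 11 higher and 0 lower for the DNA replication genes. In all 3133 genes passed, 1567 higher and 1566 lower, and with the deposited values the median gene shifted by 0.18.

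In the Pdgf Cre tumour all 18 of 18 mitosis genes rose over cortical Olig2 cells (median log2 difference 4.37, or 3.59 at the dim limit, camera adjusted p = 4.3e-05, and adjusted p = 0.769 with an estimated correlation). Plk1 rose at least 5.85-fold, Ccnb2 23.7-fold (log2 difference 4.57 ± 0.63 SE), Ccna2 17.8-fold and Cdk1 17.5-fold. DNA replication genes rose in 13 of 14 (median log2 difference 2.38, camera adjusted p = 0.00112, and adjusted p = 0.734 with an estimated correlation). Cdc45 rose 16.02-fold. Antigen presentation genes rose in 11 of 12 (median log2 difference 3.52, or 1.90 at the dim limit, camera adjusted p = 0.0564). Psmb8 rose at least 28.4-fold, though 1 of the 3 arrays held the highest levels (10.33 against 6.74 and 6.34). The interferon-induced GTPase gene Igtp rose 24.2-fold and Vim 17.7-fold. Myelin markers fell in 14 of 14 (median log2 difference -5.06, camera adjusted p = 8.88e-07, and adjusted p = 0.553 with an estimated correlation). Opalin fell 103-fold (log2 difference -6.69 ± 0.75 SE), Ermn 84.9-fold, Mog 75.8-fold and Mag 48.7-fold, and Id4, an inhibitor of bHLH factors, fell 47.6-fold. Counts for these lists were the same when adjusted over the list alone except 14 higher and 0 lower for the DNA replication genes. In all 3534 genes passed, 49.2% higher, but 41.96% with the deposited values and 61.98% with spike-in scaling, so the balance turns with the scale.

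In the Recruited tumour 4 of 14 myelin markers fell below cortical Olig2 cells and 10 did not pass (median log2 difference -0.65, camera adjusted p = 0.284). Its arrays differed, at list means of 10.78, 11.90 and 12.86 against 12.67 ± 0.08, and without pair 3 the median was -1.12. Opalin fell 4.07-fold and Aspa 3.71-fold, and Cnp did not pass (log2 difference -0.83 ± 0.45 SE, adjusted p = 0.122). Astrocyte markers rose in 6 and fell in 2 of 14 (median log2 difference 0.88, camera adjusted p = 0.111). Slc1a3 rose 4.72-fold and S100b fell 3.02-fold. Extracellular matrix and mesenchymal genes rose in 10 of 11 (median log2 difference 3.47, or 1.32 at the dim limit, camera adjusted p = 0.00112, and adjusted p = 0.701 with an estimated correlation). Lgals3 rose at least 5.02-fold, Sparc 11.3-fold (log2 difference 3.49 ± 0.38 SE) and Vim 10.6-fold. Mitosis genes rose in 10 of 18 (median log2 difference 2.35, or 1.27 at the dim limit, camera adjusted p = 0.00959, and adjusted p = 0.968 with an estimated correlation). Aurka rose at least 3.45-fold. Ifitm3 rose 18.7-fold, Hpgd 16.3-fold and H2-K1 10.8-fold, while Lad1 fell 14.4-fold (log2 difference -3.85 ± 0.37 SE), Serpinb1a 14.3-fold and the neuropeptide gene Cck 8.23-fold. With the replicate number as a block, a number not shown to link cortex and tumour arrays, Aspa, Cck, H2-K1, Hpgd, Ifitm3, Lad1, Opalin and Slc1a3 did not pass. Counts for these lists were the same when adjusted over the list alone except 11 higher and 0 lower for the mitosis genes. In all 2694 genes passed, 46.96% higher, but 63.7% with the deposited values, where the median gene shifted by 0.23.

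The stage of the tumour cells was asked of 2 sets of 200 genes that passed between progenitors and mature oligodendrocytes, those with the largest moderated t on each side. In tumour against cortical Olig2 cells the genes high in progenitors shifted up with a median log2 difference of 0.33 (53 higher, 20 lower; camera p = 0.000112, and p = 0.132 with an estimated correlation). Genes high in mature cells shifted down by -0.70 (6 higher, 83 lower; camera p = 1.17e-20, and p = 0.00262 with an estimated correlation). By model, the medians of progenitor genes were 0.72 for Pdgf (p = 0.0455 with an estimated correlation), 0.43 for Pdgf Cre (p = 0.214) and 0.00 for Recruited (p = 0.69). Those of mature genes were -0.91 (p = 0.000722 with an estimated correlation), -0.76 (p = 0.00933) and -0.48 (p = 0.0308). Over all models the progenitor median was 0.68 with only the groups compared, 0.75 with the replicate block and 0.73 with spike-in scaling, and the mature one -0.17 with no filter on dim genes, -1.17 with a dim limit of 100 and -1.47 with spike-in scaling. With sets chosen anew they were 0.53 and -1.07 without Recruited bound array 3, and 0.76 and -1.06 without pair 3. The sets carry the 3′ difference between progenitor and mature arrays given above.

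The models were compared with one another in bound RNA (n = 3 each). Between Pdgf Cre and Pdgf tumours, Ddx6, an RNA helicase gene, was 20.5-fold (log2 difference 4.36 ± 0.58 SE) higher with Cre, Hnrnpr 10.1-fold, and the division genes Incenp, Kif18b and Plk4 6.76-fold, 6.50-fold and 5.64-fold. Mitosis genes rose in 7 of 18 (median log2 difference 1.62, camera adjusted p = 0.00883, and adjusted p = 0.968 with an estimated correlation). Tpx2 rose 5.37-fold and Plk1 4.60-fold. Myelin markers rose in 8 and fell in 1 of 14 (median log2 difference 2.04, or 0.44 at the dim limit, camera adjusted p = 0.0322, and adjusted p = 0.899 with an estimated correlation). Mal rose at least 8.37-fold and Trf 5.60-fold. The stress gene Sesn2 rose at least 13.7-fold. Klhl4 fell 9.69-fold (log2 difference -3.28 ± 0.77 SE), Trnp1 9.11-fold and Robo1 5.90-fold. With the replicate number as a block Klhl4, Mal, Robo1 and Trf did not pass. Counts for these lists were the same when adjusted over the list alone. In all 1630 genes passed, 46.7% higher with Cre; the share was 29.3% with the deposited values (median gene shifted by -0.21) and 69.4% with spike-in scaling, so the balance of rises and falls rests on the scaling.

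Against the Pdgf tumour, bound RNA of the Recruited tumour was rich in genes of myelin and of astrocytes (n = 3 each). Fam107a, Trf and Gja1 were higher by 102-fold (log2 difference 6.67 ± 0.24 SE), 91.8-fold (log2 difference 6.52 ± 0.47 SE) and 82.5-fold, and Selenop, Mgst1 and Ptgds by 40.8-fold, 31.3-fold and 29.4-fold. Myelin markers rose in 13 of 14 (median log2 difference 6.0, or 4.51 at the dim limit, camera adjusted p = 1.67e-08, and adjusted p = 0.47 with an estimated correlation). Mal rose at least 268-fold and Mog at least 247-fold. Astrocyte markers rose in 10 of 14 (median log2 difference 2.45, or 1.84 at the dim limit, camera adjusted p = 1.44e-07, and adjusted p = 0.231 with an estimated correlation). Gjb6 rose at least 52.3-fold. Committed precursor markers rose in 5 of 9 (median log2 difference 1.40, or 0.96 at the dim limit, camera adjusted p = 0.0114, and adjusted p = 0.701 with an estimated correlation). Hedgehog pathway genes rose in 2 of 5 (median log2 difference 0.80, or 0.12 at the dim limit, camera adjusted p = 0.00398, and adjusted p = 0.311 with an estimated correlation). Hhip rose at least 1.40-fold. DNA replication genes fell in 8 of 14 (median log2 difference -1.89, or -1.55 at the dim limit, camera adjusted p = 0.0253, and adjusted p = 0.899 with an estimated correlation). Cdc45 fell 6.30-fold and Mcm3 5.25-fold, and the licensing gene Cdt1 fell 8.15-fold. Meox1 fell 15.02-fold (log2 difference -3.91 ± 0.74 SE). Progenitor markers fell in 3 of 11 (median log2 difference -0.61, camera adjusted p = 0.438). C1ql1 fell at least 12.4-fold. With that block Cdt1 and Mcm3 did not pass. Counts for these lists were the same when adjusted over the list alone except 0 higher and 9 lower for the DNA replication genes. In all 2524 genes passed, 1250 higher and 1274 lower.

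Against the Pdgf Cre tumour the Recruited tumour showed more of myelin and less of division (n = 3 each). Mog was higher by 67.7-fold (log2 difference 6.08 ± 0.82 SE), Mag by 33.1-fold, Ermn by 33.1-fold, Gja1 by 57.95-fold (log2 difference 5.86 ± 0.19 SE) and Sparc by 28.4-fold. Myelin markers rose in 13 of 14 (median log2 difference 4.37, or 4.25 at the dim limit, camera adjusted p = 1.3e-05, and adjusted p = 0.649 with an estimated correlation) and astrocyte markers in 11 of 14 (median log2 difference 1.98, or 1.66 at the dim limit, camera adjusted p = 2.86e-05, and adjusted p = 0.342 with an estimated correlation). Gjb6 rose at least 52.3-fold. Mitosis genes fell in 12 of 18 (median log2 difference -2.15, or -1.91 at the dim limit, camera adjusted p = 0.0271, and adjusted p = 0.979 with an estimated correlation). Ccnb2 fell 9.28-fold and Cdk1 8.16-fold. DNA replication genes fell in 10 of 14 (median log2 difference -2.13, camera adjusted p = 0.00337, and adjusted p = 0.769 with an estimated correlation). Cdc45 fell 17.7-fold and Cdt1 20.6-fold (log2 difference -4.36 ± 0.66 SE). Irf8 fell 17-fold. With that block Ccnb2, Cdt1, Irf8, Mag and Mog did not pass. Counts for these lists were the same when adjusted over the list alone except 0 higher and 11 lower for the DNA replication genes. In all 3378 genes passed, 50.7% higher; the share was 70.9% with the deposited values (median gene shifted by 0.30) and 34.01% with spike-in scaling.

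Total RNA of the tumours was set against total RNA of cortex to see the change of the whole tissue (n = 9 against 5). Pdgfra rose at least 59.2-fold, Olig2 42.4-fold (log2 difference 5.41 ± 0.27 SE), Cd9 67.3-fold (log2 difference 6.07 ± 0.33 SE), Spry1 54.8-fold, the protease gene Ctsc 58.6-fold, Vim 31.3-fold and Anxa1 30.5-fold. All 18 of 18 mitosis genes rose (median log2 difference 5.61, or 2.16 at the dim limit, camera adjusted p = 7.99e-06, and adjusted p = 0.734 with an estimated correlation). Nusap1 rose at least 14.9-fold. All 11 of 11 progenitor markers rose (median log2 difference 3.62, or 2.12 at the dim limit, camera adjusted p = 0.000213, and adjusted p = 0.701 with an estimated correlation). Lhfpl3 rose 23.6-fold. All 11 of 11 microglia markers (median log2 difference 3.81, or 2.69 at the dim limit, camera adjusted p = 0.000933, and adjusted p = 0.719 with an estimated correlation) and 10 of 10 pericyte, smooth muscle and fibroblast markers (median log2 difference 3.71, or 1.57 at the dim limit, camera adjusted p = 0.00434, and adjusted p = 0.644 with an estimated correlation) rose, with C1qb up 23.4-fold and Col3a1 at least 16.9-fold. So did 11 of 11 extracellular matrix genes (median log2 difference 4.72, or 3.09 at the dim limit, camera adjusted p = 0.000519, and adjusted p = 0.665 with an estimated correlation) and 11 of 12 antigen presentation genes (median log2 difference 4.97, or 2.04 at the dim limit, camera adjusted p = 0.0253, and adjusted p = 0.958 with an estimated correlation). Fn1 rose at least 16.77-fold and H2-D1 40.9-fold. All 13 of 13 neuron markers fell (median log2 difference -3.17, or -2.69 at the dim limit, camera adjusted p = 0.00143, and adjusted p = 0.719 with an estimated correlation). Tbr1 fell 33.4-fold, and the calcium pump gene Atp2b2 fell 53.6-fold (log2 difference -5.74 ± 0.32 SE) and Vip 30.3-fold. Counts for the lists in total RNA were the same when adjusted over the list alone. In all 4636 genes passed, 48.04% higher, but 64.1% with the deposited values, where the median gene shifted by 0.24.

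The ratio of bound to total RNA was compared between tumour and cortical Olig2 cells to ask whether the cells stand out from their tissue as much (n = 9 and 9 tumour arrays against 3 and 5). Genes of the lineage stood out less in tumours. All 11 of 11 progenitor markers had a lower ratio (median log2 difference -3.16, or -1.71 at the dim limit, camera adjusted p = 0.000799, and adjusted p = 0.71 with an estimated correlation), Lhfpl3 by a log2 difference -3.86 ± 0.49 SE, while Matn4 and Cspg4 were dim in cortex total RNA. Myelin markers were lower in 13 of 14 (median log2 difference -3.34, or -2.96 at the dim limit, camera adjusted p = 0.000487, and adjusted p = 0.719 with an estimated correlation), Cldn11 by a log2 difference -3.74 ± 0.38 SE, committed precursor markers in 8 of 9 (median log2 difference -3.02, or -2.63 at the dim limit, camera adjusted p = 0.000699, and adjusted p = 0.49 with an estimated correlation), Gpr17 by a log2 difference -3.77 ± 0.48 SE, and mitosis genes in 13 of 18 (median log2 difference -2.27, or -0.17 at the dim limit, camera adjusted p = 0.0467, and adjusted p = 0.979 with an estimated correlation), of which Cdk1 was dim in cortex total RNA. Pericyte, smooth muscle and fibroblast markers were lower in 8 of 10 (median log2 difference -2.81, or -1.48 at the dim limit, camera adjusted p = 0.0228, and adjusted p = 0.71 with an estimated correlation), and Col3a1 was dim in both RNAs of cortex. Neuron markers were higher in 6 and lower in 1 of 13 (median log2 difference 1.25, or 1.77 at the dim limit, camera adjusted p = 0.463), and Syt1 was dim in both RNAs of the tumours. Counts for the lists of this ratio were the same when adjusted over the list alone except 0 higher and 9 lower for the pericyte, smooth muscle and fibroblast markers. In all 4295 genes passed, 49.7% higher, and 35.3% with the deposited values, where the median gene shifted by -0.19. The ratio also parted the models from each other, in 1209 genes for Pdgf Cre against Pdgf, 2943 for Recruited against Pdgf and 2617 for Recruited against Pdgf Cre. In fits of only the groups compared, added after the data were seen, these were 1247, 1744 and 1713, and with the pair as a block as well 1459, 2111 and 1929.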

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

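Tests here were chosen only after the result was seen, except the planned single-array omissions, deposited scale and tumour against cortex ratio.

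In cortex total RNA, the group with 5 arrays, 28 of 100 values checked held 1 array far from the other 4 by Dixon's ratio. Values of 1 array are not independent, and for Matn4, Col3a1 and Smo, at the floor, the ratio says little. The genes, with the log2 level of the array that stood apart, were replicate 1, Bmp4 6.14, Nefl 13.19, Rrm2 5.12; replicate 2, Cnksr3 8.10, Col3a1 2.18, Matn4 2.09, Rbfox3 12.01, Snap25 15.10; replicate 3, Gja1 12.60, Mdk 5.57, Pdgfra 4.91, Slc1a3 8.05, Ttr 11.999, Tuba8 5.78; replicate 4, C1qb 7.75, Gad2 6.45, Hey2 6.38, Smo 2.72; replicate 5, Cd9 6.66, Fn1 3.60, Id1 4.59, Lims2 7.19, Mag 7.19, Mobp 4.58, Pfn1 7.18, Ppil1 6.83, S100a1 8.15. Replicate 5 was also the array with the lowest actin 3′ minus 5′ difference, 2.80, where the others lay between 4.70 and 5.32. Leaving replicate 5 out gave 2802 genes against 2765 for neurons, 5966 against 5973 for astrocytes, 5178 against 5181 for mature oligodendrocytes, 4693 against 4722 for progenitors and 5492 against 5498 for cortical Olig2 cells. Ttr in replicate 3, at 11.999 against 4.85 for the next, was the widest of these gaps.

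A difference between groups in the ratio of bound to total RNA was tested by an interaction term, and passed in 4295 genes for tumours against cortical Olig2 cells, 1209 for Pdgf Cre against Pdgf, 2943 for Recruited against Pdgf and 2617 for Recruited against Pdgf Cre. Of the control probes outside the comparisons, the 3′ minus 5′ difference of actin (6.48) and of Gapdh (6.14) was higher in progenitor arrays than in cortex total RNA, so the levels of long transcripts in progenitors may read low on probes far from the 3′ end. That bears on the mitosis genes weighed below, which lay 2.12 higher in tumour Olig2 cells than in progenitors.

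The myelin and astrocyte genes stood higher in bound RNA of the Recruited tumour than in the other models, by a median log2 difference of 3.43 over 28 genes. Without pair 3 it was 3.40, which argues against that pair as the source. Carry-over of total RNA would leave no gap between bound and total RNA; the myelin genes lay 2.27 above total RNA, with 12 of 14 higher, but the astrocyte genes only 0.49, with 4 higher, so carry-over stays open for those. A mixture with normal Olig2 cells of the surrounding brain could give myelin levels at or under those cells, as found in the median (-0.65, and -1.12 without pair 3) though not in array 3, but not astrocyte genes above them in all 3 arrays (0.88). The spread between its arrays is wide, and the Recruited tumour may hold Olig2 cells nearer to normal myelinating cells, or normal cells within its borders, and the arrays cannot part these.

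Mitosis genes stood 3.11 higher in tumour than in cortical Olig2 cells over 18 genes. Scaling does not account for it, since the lower of the medians on other scales was 3.105. Carry-over from dividing cells of other kinds would leave bound RNA far below total RNA, as for microglia genes. Bound minus total was 0.45 here, 0.034 with the deposited values and 0.093 with spike-in scaling. Its size rests on the scale, but a deep depletion is argued against. The tumour level lay 2.12 above progenitor bound RNA, which also holds myelin genes, so a larger progenitor share stays open. More division within tumour Olig2 cells may explain the rise. The 3′ bias of progenitor arrays bears on the 2.12, not on the 3.11.

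Antigen presentation and microglia genes stood higher in bound RNA of tumours than of cortical Olig2 cells. Bound minus total was -5.01 for the microglia genes (1.42 higher) and -2.81 for the class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 (3.16 higher). The former fits carry-over; the latter is less deep on every scale, so carry-over from microglia alone stays open for class II. For class I and peptide loading genes (3.12 higher) bound minus total was 0.34, and -0.103 with the deposited values, which argues against carry-over from microglia as their source. The lower median on other scales was 3.14, which does not test the floor. The rise was uneven, highest in 1 array each of Pdgf Cre and Recruited. Tumour Olig2 cells may express class I genes themselves, while their microglia signal is likely that of other cells.

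Other splits of the same arrays were also fitted, with only the arrays compared and the 3 models pooled as 1 group where their mean was tested, and all of these tests were chosen after the results were seen. The real split gave the largest count, 1 of 56, for neurons (2833, highest other 0), astrocytes (5996, highest other 0), mature oligodendrocytes (5227, highest other 0), progenitors (4750, highest other 0) and cortical Olig2 cells (5529, highest other 1). With 10 splits there are too few for a share under 0.05; the real value and the highest other were 3851, highest other 0 for progenitors against mature oligodendrocytes, 2977, highest other 0 for Pdgf bound against total RNA, 3670, highest other 0 for Pdgf Cre, 2923, highest other 0 for Recruited, 3092, highest other 0, 3532, highest other 0 and 2213, highest other 0 for these models against cortical Olig2 cells, 1573, highest other 0 for Pdgf Cre against Pdgf, 1990, highest other 0 for Recruited against Pdgf and 2971, highest other 0 for Recruited against Pdgf Cre. Of 100 splits, only the real one reached the real count for tumour against cortical Olig2 cells (1835, highest other 291), tumour against cortex total RNA (4334, highest other 1645) and the difference of ratios (3090, highest other 1171). For genes high in progenitors 10 of 100 splits reached the median of 0.33, so chance is not excluded for that shift; for genes high in mature cells 1 of 100 reached -0.70, the highest other being 0.52.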

How the results depend on the processing

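Spike-in scaling, the omission of pair 3 of the Recruited tumour and the pair block for ratios between models were chosen only after the data were seen, and the other settings were planned. Most results kept direction and side of the threshold, though p values can be too small in all settings because of the separate GCRMA. With the deposited values the neuron comparison passed 4774 genes against 2765. With the replicate block, Recruited against Pdgf passed 1681 against 2524 (1990 with only the groups compared) and against cortical Olig2 cells 1798 against 2694. No cause was tested. Other counts of the 18 comparisons stayed within 1.5 times in each setting. Ratios between models did not. Of 3157 genes in Pdgf bound against total RNA, 2083 also passed as deposited. Of the differences of named genes, 0 reversed; 3 became weaker with the deposited values, 3 with spike-in scaling, 16 with only the groups compared and 22 with the replicate block, which also has fewer arrays. Only those of the block are listed. Lists whose camera p before adjustment lay under 0.05 only without the block were the BMP and TGF-beta pathway genes and the ependymal and choroid plexus markers in astrocytes, the Wnt pathway genes and the committed oligodendrocyte precursor markers in tumour against cortical Olig2 cells and the mature oligodendrocyte and myelin markers in Pdgf Cre against Pdgf.

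List medians that changed sign were all small ones with no test passed. They were the ribosomal protein genes in progenitors against mature oligodendrocytes (-0.15 with the deposited values, -0.25 with spike-in scaling), the mitosis genes in Pdgf bound against total RNA (-0.32 with the deposited values, -0.22 with spike-in scaling) and the p53 target genes in tumour against cortical Olig2 cells (0.028 with the deposited values, 0.038 with spike-in scaling); the cause was not tested. Leaving out 1 array in turn, the neuron markers in neurons ranged from -0.036 to 0.078 and the mitosis genes in Pdgf bound against total RNA from -0.069 to 0.462.

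Leaving out 1 array in turn, the counts of genes ranged from 2669 to 2802 in neurons, 5933 to 5982 in astrocytes, 5126 to 5191 in mature oligodendrocytes, 4659 to 4728 in progenitors, 5435 to 5546 in cortical Olig2 cells and 3632 to 3825 in progenitors against mature oligodendrocytes. In bound against total RNA they ranged from 3009 to 3198 in Pdgf, 3491 to 3799 in Pdgf Cre and 4215 to 4568 in Recruited. Against cortical Olig2 cells they ranged from 2647 to 2869 for all models, 3046 to 3136 for Pdgf, 3436 to 3501 for Pdgf Cre and 2465 to 3076 for Recruited. Between models they ranged from 1483 to 1700 for Pdgf Cre against Pdgf, 2338 to 2749 for Recruited against Pdgf and 3231 to 3681 for Recruited against Pdgf Cre, in total RNA from 4504 to 4845, and for the difference of ratios from 4197 to 4539. The median of genes high in progenitors ranged from 0.30 to 0.53 (without Recruited bound array 3) and that of genes high in mature cells from -1.07 (without the same array) to -0.65. Without pair 3 the Recruited tumour differed from cortical Olig2 cells in 3212 genes. In bound against total RNA, the pair as a block gave 3169 genes for Pdgf, 3756 for Pdgf Cre and 2947 for Recruited, where only the groups compared gave 2923. Averaging several probe sets of a gene could change nothing, since each gene had 1. Signal near background limits the folds of dim genes, so a fold with 1 dim side is given as a lower bound; list counts and list medians without the dim limit have no such bound.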

Other observations

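The genes of this part were chosen only after their values were seen, and no test of a cause was made.

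Genes of the sex chromosomes differed between tumour models. Eif2s3y, on the Y chromosome, stood at 9.49 ± 0.19 in bound and 10.74 ± 0.19 in total RNA of the Pdgf tumour and at 2.08 ± 0.00 and 2.08 ± 0.00 in the Pdgf Cre tumour. In the Recruited tumour it stood at 7.40 ± 4.69 and 8.15 ± 3.93, with the spread between its arrays far above that in the other models. Xist, the RNA of the silenced X chromosome, stood at 7.77 ± 0.01 in Pdgf Cre total RNA, 2.08 ± 0.00 in Pdgf and 2.42 ± 0.41 in Recruited total RNA. Comparisons between the Pdgf and Pdgf Cre tumours thus also set arrays with and without a Y-chromosome signal against each other.

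H19, an imprinted noncoding RNA, stood at 2.08 ± 0.00 in cortex total RNA and at 11.33 ± 0.49, 10.53 ± 1.10 and 12.16 ± 0.65 in total RNA of the Pdgf, Pdgf Cre and Recruited tumours, while the bound RNA held 6.01 ± 0.01, 6.67 ± 0.84 and 6.48 ± 1.01. It fell 39.97-fold and 51.2-fold in bound against total RNA of the Pdgf and Recruited tumours. Wsb1 stood at 12.30 ± 0.33, 12.06 ± 0.69 and 12.64 ± 0.87 in the same total RNA and at 8.71 ± 0.19, 7.73 ± 0.48 and 8.40 ± 0.22 in bound RNA.

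Ttr, whose main source in the brain is the choroid plexus, varied more between arrays than between many groups, at 5.44 ± 1.67 in mature oligodendrocytes, 10.96 ± 0.07 in cortical Olig2 cells, 6.24 ± 3.07 in Pdgf bound RNA and 10.28 ± 3.43 in Recruited bound RNA. Arrays of Recruited total RNA also spread widely in lists of cell types, with mitosis genes at 6.82 ± 2.87 and microglia markers at 9.11 ± 1.87, against 7.24 ± 0.32 and 10.36 ± 0.17 in the Pdgf tumour.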
